A study of Mus musculus with 6 samples.

How the data were processed

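The series measured poly-A RNA of CD8 T cells sorted from MC38-hPD-L1 tumours, in 3 Biotin+ and 3 Biotin- samples from C57BL/6N mice. RNA was purified with poly-T beads, fragmented and reverse transcribed from random hexamers, per the labels' protocols, which name no unique molecular identifiers and no strand setting. The deposited table holds raw counts of reads per gene symbol, 1 column per sample, per the labels and the whole-number values. Trim Galore 0.6.7, STAR 2.7.10a, Picard 1.14 and featureCounts 2.0.1 with the GRCm39 genome are named in the submitters' processing notes, without the role of each. The gene annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The reference used here was GENCODE M21 on GRCm38, another build, so it served only for symbols, transcript sequences, GC content and transcript length, and no coordinates are given.

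Samples were mapped to groups and replicate numbers by their titles. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples. The replicate numbers differed in their shares of T cell receptor beta V segments (below). This argues against technical replicates of a single pool of cells, but whether a number marks an animal or a pool of animals is not given. Every pair of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 35.6 to 102.7), and all 6 were kept. The table held 40879 genes, of which 18545 had no count in any library. Totals per library were 16423106 to 19640693 counts, and reads without molecular identifiers are not independent molecules, so that counting error is a lower limit of the error.

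The main test, fixed before the data were examined, was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; filterByExpr, TMM normalization, robust dispersion and glmQLFit, design with the group alone), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are Biotin+ minus Biotin-, SE is the log2 fold change divided by the root of F, and CPM are TMM-scaled, with mean and SD over 3 libraries. The common biological coefficient of variation was 0.311. The 28 gene lists, also fixed beforehand, were tested with camera in limma 3.58.1 (preset correlation 0.01, lists of at least 3 tested genes, adjustment over the 28 lists), and each list's members are also counted with p-values adjusted over the list alone. With an estimated correlation camera called 0 lists, with 3 at an unadjusted p below 0.05, so that each list call rests on the preset correlation. fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, called 2 lists (naive and memory, fibroblast and endothelial), and its test for change in either direction 13. The lists were CD8 T identity, cytotoxic effectors, inhibitory receptors and exhaustion, naive and memory, tissue residency, circulating effector, T cell receptor signalling, immediate early and dissociation stress, chemokines and chemokine receptors, cell cycle, type I and gamma interferon response, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, oxidative stress, unfolded protein response, cytosolic ribosomal proteins, T cell receptor V segments, and markers of epithelial and tumour cells, macrophages and monocytes, dendritic cells and MHC class II, neutrophils, B cells, CD4 T cells, NK and gamma delta T cells, and fibroblasts and endothelium. Of the list genes, 22 were found in the table under another symbol, and Zfp683 was not analysed here.

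The genes named in the text follow a rule fixed beforehand: the 10 higher and 10 lower genes with the largest log2 fold change among those that passed, with a mean CPM of at least 10 and group ranges that do not overlap, without predicted gene models and receptor segments; up to 4 members of each list with the smallest p; and Cd8a, Pdcd1, Havcr2, Lag3, Tox, Gzmb, Prf1, Ifng, Mki67, Tcf7, Ccr7, Il7r, Cxcr6 and Itgae. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

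Both groups carry replicate numbers 1 to 3 in their titles. Deviations of log2 CPM from the group means correlated at 0.366, 0.263 and 0.393 across genes for samples with the same number, and at -0.0721 to -0.276 for samples with different numbers, so the numbers were taken to pair the samples. Values with the number as a block are printed beside a result where they change its call or move a count by over 1.5 times.

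Alternatives fixed beforehand were DESeq2 size factors, upper quartile and library size scaling in edgeR, no filter and a filter of CPM 1 in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, the replicate block, a table without mitochondrial, T cell receptor and immunoglobulin segment genes, an adjusted p of 0.01, a test against a fold of 1.5, each library and each same-numbered pair left out, and for lists the estimated correlation, fry and the block. Chosen after the data were seen were a scaling of each library to the median of the CD8 T identity list (the identity scaling), an offset that removes a spline trend of each library on GC content and transcript length (96.2% of the tested genes had both), and each of these with the block. Sequence shared with other genes was measured as the percentage of 75-base windows of a gene's transcript found in transcripts of other genes. Windows that the checked genes share only with each other, as granzymes can, were not counted.

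The tests were run on simulated data, with counts drawn for 13360 genes from the means, dispersions and library sizes of these samples. After the filter 13066 genes were tested, 198 of them changed, a smaller share than was called in the real data (1103 of 13360). For Biotin+ against Biotin-, 22.4% of the genes changed 2-fold and 76% of those changed 4-fold were recovered, 13 of 111 calls were unchanged genes, and camera called 0 of 20 unchanged lists. With the replicate block 18 unchanged genes were called, and fry called 1 of the 20 unchanged lists. Genes were drawn independently of each other and samples without a pair effect. The simulation therefore cannot show how the list tests behave with correlated genes, or the block with paired samples.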

Results

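CD8 T cells were sorted from MC38-hPD-L1 tumours of C57BL/6N mice on day 12 and profiled by poly-A RNA sequencing. MC38 is a mouse colon carcinoma line. The cells had been exposed to proximity labelling with a deep-red photocatalyst, a method in which light drives the attachment of biotin to cells near the catalyst, and flow cytometry then parted them into cells that carried biotin (Biotin+, described in the labels as neighbouring the tumour) and cells that did not (Biotin-, described as distal to it). Each group held 3 libraries, numbered as replicates 1 to 3. Total counts ranged from 16440614 to 19640693 per library in Biotin+ and from 16423106 to 19035864 in Biotin-.

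The Biotin- libraries held more kinds of transcript. Between 18142 and 18477 genes had a count in each Biotin- library, against 15780 to 16213 in each Biotin+ library, at similar totals. The first principal component of log2 CPM carried 54.6% of the variance and placed the 3 Biotin+ libraries on the other side of the 3 Biotin- libraries. The second carried 17.5% and placed replicates 1 and 3 of both groups at opposite ends. Biotin+ replicate 2 stood apart in its share of cytosolic ribosomal protein transcripts, 18.0% of its counts against 12.8% to 14.1% in the other 5 libraries, and it also had the lowest TMM scaling factor (0.815). Transcripts of the fibroblast and endothelial marker list took 0.0423 ± 0.0144% of the counts in Biotin+ and 0.235 ± 0.0736% in Biotin- (SD, n = 3 each).

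The design holds a single comparison, which asks how intratumoral CD8 T cells that neighbour tumour cells differ in expression from those that lie farther away. Perforin, 7 of 9 granzymes and several inhibitory receptors were higher in the Biotin+ libraries. In the same libraries 10 of 24 naive and memory T cell genes (Tcf7 and S1pr1 among them), 5 of 25 early response genes and many extracellular matrix genes were lower. All 15 CD8 T cell identity genes had positive log2 fold changes too (median 0.69). With libraries scaled to these genes, 6 of the 18 cytotoxic and inhibitory receptor members called higher stayed so, Pdcd1 and Tnfrsf9 among them, and 10 with the replicate block. Of 13360 genes tested, 1103 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 205 of them higher and 898 lower in Biotin+. With the replicate number as a block (the blocked fit), 748 were higher and 1599 lower. A fold change of at least 2 was reached by 126 of the higher and 866 of the lower genes. The CPM ranges of the groups did not overlap for any of the 1103 genes, nor for 29.2% of all tested genes, where chance gives 10% for 3 against 3.

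The higher share of the calls, 18.6%, depended on the scaling. When each library was scaled to the median of 15 CD8 T cell identity genes, an alternative chosen after the data were seen, the median log2 fold change of all genes moved by -0.802, and 21 genes were higher and 4273 lower (0.489% higher). Counts also moved with single libraries: the number of higher genes was 58 without Biotin+ replicate 2, 52 without Biotin- replicate 1, 111 without Biotin- replicate 2 and 23 without Biotin- replicate 3, and the number of lower genes was 364, 445, 843 and 239 in the same order.

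**Figure D1:**
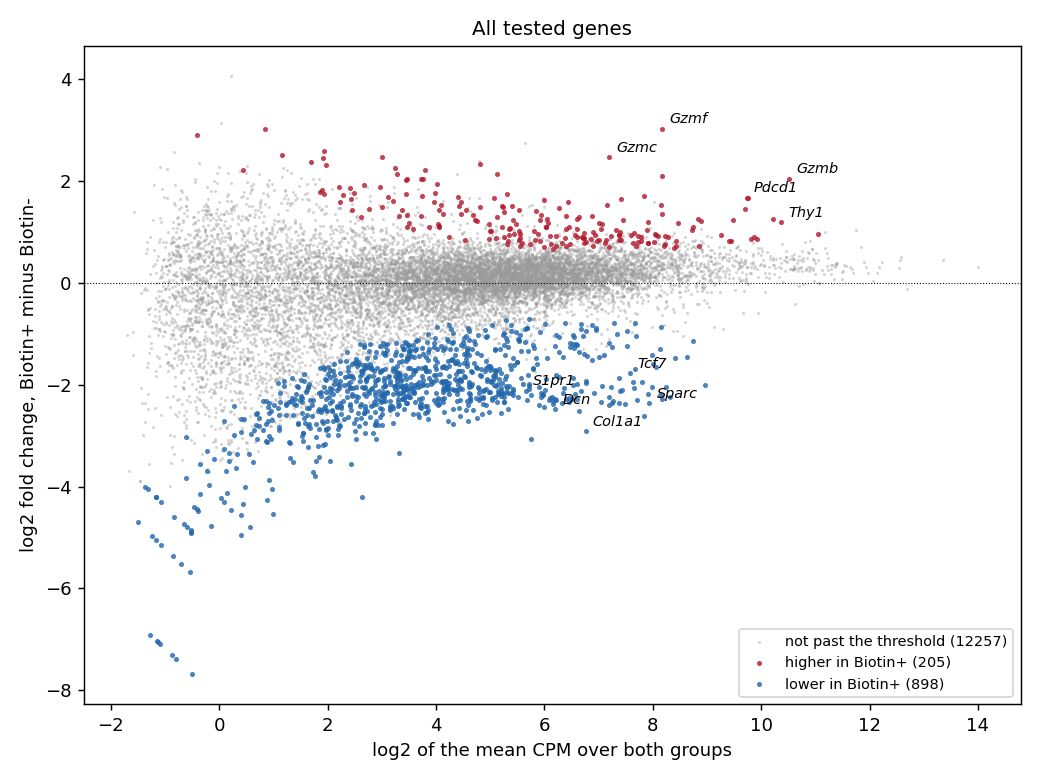
Log2 fold change (Biotin+ minus Biotin-) of each of the 13360 tested genes against the log2 of its mean CPM over both groups. Red points are the 205 genes called higher, blue points the 898 called lower and grey points the genes that did not pass, and the calls on the lower side outnumber those on the higher side.

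Among genes with a mean CPM of at least 10, the largest increases in Biotin+ were those of the granzymes Gzmf, Gzmc, Gzme, Gzmd and Gzmb, together with Gldc (a glycine cleavage enzyme), Ifitm1 (an interferon-induced membrane protein), Ly6g5b, Ptpn5 (a tyrosine phosphatase) and Serpinb9b (a serpin). Their log2 fold changes ran from 3.03 ± 0.37 (SE) for Gzmf down to 2.02 ± 0.44 (SE) for Serpinb9b. Gzmf averaged 513 ± 64.1 CPM in Biotin+ and 62.7 ± 32.5 CPM in Biotin- (SD, n = 3, edgeR adjusted p = 0.00554). The largest decreases were those of the fibrillar collagen chains Col1a2, Col1a1, Col5a2 and Col3a1, the matrix cross-linking enzymes Loxl1 and Pxdn, and Steap2, Ano1, Amotl1 and Fkbp9, from a log2 fold change of -3.07 ± 0.48 (SE) for Col1a2 to -2.61 ± 0.38 (SE) for Col3a1. Of these 20 genes, 5 lost their call when a single library was left out. Without Biotin+ replicate 2 the calls of Gzme, Gldc, Gzmd and Serpinb9b were lost, without Biotin+ replicate 1 that of Gzme, without Biotin- replicate 1 that of Serpinb9b, without Biotin- replicate 2 those of Gzme, Gzmd and Serpinb9b, and without Biotin- replicate 3 those of Gldc, Gzmd, Serpinb9b and Steap2.

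Of 24 cytotoxic effector genes tested, 12 were higher, 0 were lower and 12 did not pass, with a median log2 fold change of 0.94. Under the identity scaling 4 were higher and 3 lower, with a median of 0.136. The camera test of the list gave an adjusted p of 1.37e-11 over the 28 lists, and an adjusted p of 0.239 with an estimated correlation. Gzmb, a granule protease that triggers death of target cells, was 2369 ± 776 CPM in Biotin+ and 572 ± 199 CPM in Biotin- (SD, n = 3, log2 fold change 2.05 ± 0.33 SE, edgeR adjusted p = 0.00785). Prf1, the pore-forming perforin that admits granzymes, was 259 ± 69.1 against 82.5 ± 14.6 CPM (SD, n = 3, log2 fold change 1.65 ± 0.25 SE, edgeR adjusted p = 0.00662). Gzmc, Gzmf, Gzmb and Prf1 passed without each of the 6 libraries in turn and without each same-numbered pair. Ifng, which encodes the cytokine interferon gamma, had a log2 fold change of 0.94 ± 0.41 (SE) and did not pass (edgeR adjusted p = 0.203), but passed in the blocked fit (edgeR adjusted p = 0.000983).

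The count of cytotoxic genes adjusted over the list alone was 14 higher and 1 lower, and 17 were higher and 1 lower in the blocked fit. The lower gene in both was the granzyme Gzmm, named after its values were seen, which did not pass in edgeR (log2 fold change -1.44 ± 0.43 SE, edgeR adjusted p = 0.0678; 0.00183 in the blocked fit). Of the 9 granzymes, a family chosen after the data were seen, 7 were higher and 2 did not pass in edgeR, and DESeq2 gave 7 higher and 1 lower. Transcripts of the list took 0.837 ± 0.118% of the counts in Biotin+ and 0.441 ± 0.0781% in Biotin- (SD, n = 3), in libraries where fibroblast and endothelial marker transcripts took 0.0423% and 0.235%. The number of higher members was 5 without Biotin+ replicate 2, 7 without Biotin- replicate 1 and 5 without Biotin- replicate 3. Gzmf shared 9.5% of its 75-base windows with transcripts of other genes and its counts are uncertain to at least that extent, while Gzmb, Gzmc, Gzmd, Gzme and Prf1 shared none. The count left out windows that the checked granzymes (Gzmb to Gzmg and Gzmk) share with each other. It therefore cannot show whether reads of these granzymes are mixed among them.

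Inhibitory receptors and other genes linked to T cell exhaustion had a positive median log2 fold change of 0.65, which became -0.0977 under the identity scaling. Of 24 members, 6 were higher, 1 was lower and 17 did not pass, and under the identity scaling 2 were higher (Pdcd1 and Tnfrsf9) and 2 lower. Pdcd1, which encodes PD-1, was 1298 ± 570 CPM in Biotin+ and 405 ± 201 CPM in Biotin- (SD, n = 3, log2 fold change 1.68 ± 0.40 SE, edgeR adjusted p = 0.0299). Tnfrsf9, the costimulatory receptor 4-1BB, had a log2 fold change of 1.46 ± 0.24 (SE), Havcr2, which encodes TIM-3, 1.31 ± 0.32 (SE), Entpd1, the ectonucleotidase CD39, 1.27 ± 0.23 (SE), and Lag3, a receptor for MHC class II, 1.18 ± 0.26 (SE). The remaining higher member was Tigit (0.78 ± 0.20 SE), named here after its values were seen. The lower member was Layn, a hyaluronan receptor, at 1.17 ± 0.326 CPM in Biotin+ and 6.66 ± 2.41 CPM in Biotin- (SD, n = 3). Tox, a transcription factor of exhausted T cells, had a log2 fold change of 0.22 ± 0.34 (SE, edgeR adjusted p = 0.755).

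Camera gave this list an adjusted p of 6.49e-07, and the adjusted p was 0.584 with an estimated correlation. When adjusted over the list alone, 12 members were higher and 1 was lower, and in the blocked fit 14 were higher and 1 was lower. The number of higher members was 3 without Biotin+ replicate 2, 2 without Biotin- replicate 1 and 2 without Biotin- replicate 3. Tnfrsf9 and Entpd1 passed without each single library in turn, whereas Pdcd1, Havcr2 and Lag3 each lost the call without Biotin+ replicate 2, Biotin- replicate 1 or Biotin- replicate 3, Havcr2 and Lag3 also without Biotin+ replicate 3, and Lag3 also without Biotin- replicate 2. Layn lost the call without Biotin- replicate 3.

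Of 24 naive and memory genes, 10 were lower, 0 were higher and 14 did not pass, and 6 of the 24 had a positive log2 fold change (median -1.06). Under the identity scaling 15 were lower and 0 higher (median -1.85). The camera adjusted p of the list was 2.84e-08, and the adjusted p was 0.239 with an estimated correlation. Tcf7, which encodes the transcription factor TCF-1 of naive and stem-like T cells, was 87.2 ± 5.39 CPM in Biotin+ and 297 ± 30.8 CPM in Biotin- (SD, n = 3, log2 fold change -1.77 ± 0.19 SE, edgeR adjusted p = 0.00442). S1pr1, the receptor that lets lymphocytes leave tissue, changed by -2.11 ± 0.28 (SE), and Klf2, the transcription factor that induces it, by -1.64 ± 0.20 (SE). Klf3, a related transcription factor, changed by -1.92 ± 0.27 (SE). Ccr7, the chemokine receptor that guides cells to lymph nodes, had a log2 fold change of -0.76 ± 0.22 (SE) and did not pass (edgeR adjusted p = 0.0566; 0.00711 in the blocked fit). Il7r, the interleukin 7 receptor chain of memory cells, had a log2 fold change of 0.04 ± 0.30 (SE, edgeR adjusted p = 0.952).

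The counts of naive and memory genes were 14 lower and 1 higher adjusted over the list alone, and 14 lower and 2 higher in the blocked fit. Tcf7, Klf2, S1pr1 and Klf3 passed without each library and without each same-numbered pair. Fibroblast and endothelial marker transcripts were lower in the same libraries (0.0423% of counts in Biotin+ and 0.235% in Biotin-), and of the 24 members 12 are genes that stromal cells also use.

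**Figure D2:**
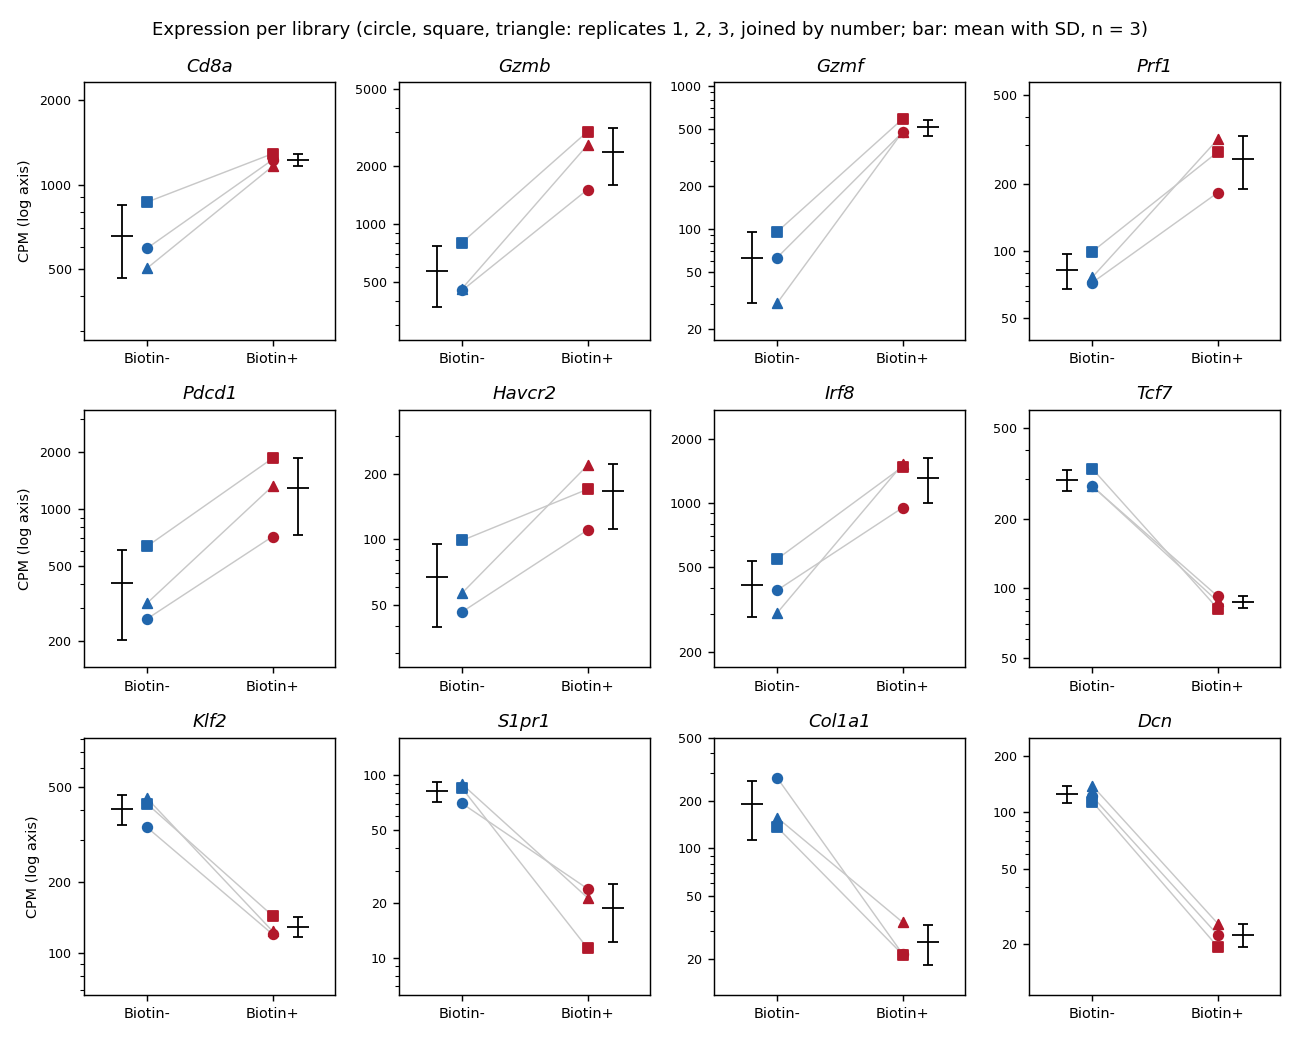
CPM per library on log axes for 12 genes, with blue symbols for Biotin-, red symbols for Biotin+, marker shapes for replicates 1 to 3, grey lines between samples that share a number, and bars for the mean with its SD (n = 3). For each of the 12 genes the ranges of the groups are apart, as for Gzmb at 2369 ± 776 against 572 ± 199 CPM and Tcf7 at 87.2 ± 5.39 against 297 ± 30.8 CPM.

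T cell receptor signalling genes moved both ways. Of 25 members, 2 were higher, 2 were lower and 21 did not pass. Irf8, an interferon regulatory factor, had a log2 fold change of 1.67 ± 0.28 (SE) and Il2ra, the high-affinity interleukin 2 receptor chain CD25, of 1.15 ± 0.27 (SE), while Myc and Egr2, transcription factors induced on activation, had log2 fold changes of -1.35 ± 0.23 and -1.51 ± 0.31 (SE). The list was not called (camera adjusted p = 0.791), and its median of 0.04 became -0.142 with library size alone. Under the identity scaling 1 was higher (Irf8) and 8 lower (median -0.748), and Il2ra did not pass (edgeR adjusted p = 0.2925). Fibroblast and endothelial marker transcripts were lower in the same libraries as Myc and Egr2 (0.0423% of counts in Biotin+ and 0.235% in Biotin-). With p-values adjusted over the list alone, 4 were higher and 4 lower, and in the blocked fit 6 were higher and 4 lower. Irf8 and Myc passed without each single library, whereas Il2ra lost the call without Biotin+ replicate 3 or Biotin- replicate 1, 2 or 3 and Egr2 without Biotin+ replicate 2 or Biotin- replicate 1 or 3.

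Early response genes included 5 lower members out of 25, with 20 that did not pass. Ier3, Egr1, Atf3 and Jun, transcripts induced within minutes of stimulation or of tissue dissociation, had log2 fold changes of -1.42 ± 0.22, -1.30 ± 0.27, -1.24 ± 0.20 and -1.13 ± 0.21 (SE). The fifth was Fosb (-0.87 ± 0.21 SE), named after its values were seen. The list was not called (median -0.17, camera adjusted p = 0.0842), with 5 lower adjusted over the list alone and 7 lower and 2 higher in the blocked fit. Under the identity scaling it was called (median -0.969, adjusted p = 5.29e-05) and 17 members were lower. Fibroblast and endothelial marker transcripts were lower in the same libraries (0.0423% of counts in Biotin+ and 0.235% in Biotin-). Its camera adjusted p was 0.00513 without Biotin+ replicate 2, 0.0243 without Biotin- replicate 1 and 0.0302 without Biotin- replicate 3, and the number of lower members was 3 without Biotin+ replicate 2 and 2 without Biotin- replicate 3. Egr1 lost the call without either of these libraries and Jun without the latter.

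Of 18 chemokines and chemokine receptors, 15 did not pass and 3 were lower: S1pr1, Cxcr5, the receptor of follicular homing (log2 fold change -2.41 ± 0.47 SE), and Cxcl10, an interferon-induced chemokine (-1.07 ± 0.20 SE). Cxcr5 averaged only 2.04 CPM in Biotin+ and 10.9 CPM in Biotin-. The list was not called (camera adjusted p = 0.331), and its median of 0.02 and mean of -0.24 differed in sign. There were 5 lower and 1 higher adjusted over the list alone, and in the blocked fit 5 were lower and 3 higher. Cxcr5 lost the call without Biotin+ replicate 2 and Cxcl10 without Biotin- replicate 3.

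Tissue residency genes had a median log2 fold change of 0.65, which became -0.142 under the identity scaling, with 1 of 14 members higher. This was Rgs1, a regulator of G protein signalling (1676 ± 389 against 705 ± 138 CPM, SD, n = 3, log2 fold change 1.25 ± 0.25 SE, edgeR adjusted p = 0.0160). Cxcr6, a chemokine receptor of resident cells, had a log2 fold change of 0.86 ± 0.25 (SE, edgeR adjusted p = 0.0608; 0.0116 in the blocked fit), and Itgae, the integrin chain CD103, of -0.48 ± 0.37 (SE, edgeR adjusted p = 0.475). Camera called the list with an adjusted p of 0.0282, and the adjusted p was 0.82 with an estimated correlation. Adjusted over the list alone, 3 were higher and 1 lower, and in the blocked fit 7 were higher and 1 lower. The camera call was lost without Biotin+ replicate 1 (adjusted p = 0.206) and without Biotin- replicate 3 (adjusted p = 0.156), and Rgs1 lost its call without Biotin- replicate 1 or 3. The number of higher members was 2 without Biotin+ replicate 3 and 3 without Biotin- replicate 2. Of 12 circulating effector genes 0 passed in edgeR, with 2 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2, 2 higher by limma-voom and 2 higher in the blocked fit. Adjusted over the list alone 2 were higher, and the list was not called (median 0.39, camera adjusted p = 0.345). Tbx21, which encodes the transcription factor T-bet, had a log2 fold change of 0.97 ± 0.30 (SE, edgeR adjusted p = 0.0761; 0.000948 in the blocked fit).

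Genes of CD8 T cell identity had positive log2 fold changes for 15 of 15 members, with a median of 0.69 that became -0.107 under the identity scaling built on these genes. Of the 15, 5 were higher and 10 did not pass. Cd3g had a log2 fold change of 1.23 ± 0.26 (SE), Thy1 of 1.20 ± 0.27 (SE), Zap70 of 1.10 ± 0.22 (SE) and Cd3e of 0.97 ± 0.24 (SE), all parts of the T cell receptor complex, its signalling or the T cell surface. Cd8a, the coreceptor used to define the population, was 1226 ± 63.6 CPM in Biotin+ and 653 ± 189 CPM in Biotin- (SD, n = 3, log2 fold change 0.91 ± 0.24 SE, edgeR adjusted p = 0.0467). Camera called the list (adjusted p = 6.06e-09; adjusted p = 0.584 with an estimated correlation). In the blocked fit 14 were higher, as when adjusted over the list alone. The number of higher members was 3 without Biotin+ replicate 1, 1 without Biotin+ replicate 2, 0 without Biotin- replicate 1 and 0 without Biotin- replicate 3, and Cd8a itself kept its call without Biotin- replicate 2 and without both samples of replicate 2, and lost it without each other library or pair.

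Growth and energy lists showed small shifts in which few members passed. Of 47 nuclear oxidative phosphorylation genes, 0 passed in edgeR, DESeq2 or limma-voom, 10 were higher at an unadjusted p under 0.05 and 5 were higher in the blocked fit. All 47 log2 fold changes were positive, with a median of 0.41, which became -0.433 under the identity scaling (camera adjusted p = 4.67e-06; adjusted p = 0.82 with an estimated correlation). Of 82 cytosolic ribosomal protein genes, 0 passed with any of the 3 tools, 2 were higher at an unadjusted p under 0.05 and 4 were higher in the blocked fit. Their median was 0.35 and became -0.487 under the identity scaling (camera adjusted p = 2.89e-06; adjusted p = 0.85 with an estimated correlation). Without Biotin+ replicate 2, the library rich in these transcripts, the median was 0.06 and the camera adjusted p 0.126. Of 44 cell cycle genes, 0 passed in edgeR or DESeq2 and 1 was lower by limma-voom, while 6 were higher and 1 lower at an unadjusted p under 0.05, and 5 higher and 1 lower in the blocked fit. Their median was 0.43 and became -0.428 under the identity scaling (camera adjusted p = 0.0178; adjusted p = 0.959 with an estimated correlation). Without Biotin+ replicate 2 the cell cycle median turned to -0.0665 (camera adjusted p = 0.425), and without Biotin- replicate 3 the camera adjusted p was 0.0558. Mki67, a marker of cycling cells, had a log2 fold change of 0.50 ± 0.31 (SE, edgeR adjusted p = 0.378). No member of these 3 lists passed when adjusted over the list alone.

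The other metabolic and stress lists were not called. Of 28 glycolysis and hypoxia genes 0 passed in edgeR (median 0.15, camera adjusted p = 0.345), with 5 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and by limma-voom, and 6 higher and 2 lower in the blocked fit, and the list passed without Biotin+ replicate 1 (adjusted p = 0.0291). Gapdh had a log2 fold change of 0.70 ± 0.27 (SE, edgeR adjusted p = 0.151; 0.0256 in the blocked fit). Of 10 mitochondrially encoded genes 0 passed in edgeR, DESeq2 or limma-voom, nor at an unadjusted p under 0.05 (median 0.12, camera adjusted p = 0.512). In COX2, COX3, ATP6, ND3 and ND4L, between 97.8% and 99.9% of 75-base windows also lay in transcripts of other genes, as did 61.5% in ND4 and 39.8% in COX1, so that their counts are uncertain. The list of 21 cholesterol synthesis genes had a median of 0.08 (camera adjusted p = 0.814). Of 25 oxidative stress genes 2 were lower (median -0.01, camera adjusted p = 0.897), with 3 lower and 2 higher in the blocked fit: Me1, malic enzyme, at -2.12 ± 0.42 (SE), and Nqo1, a quinone reductase, at -2.39 ± 0.56 (SE). Both were low in both groups, Me1 at 1.90 CPM in Biotin+ and 8.32 CPM in Biotin-, and Nqo1 at 0.751 CPM and 3.97 CPM. Of 20 unfolded protein response genes 0 passed in edgeR (median -0.01, camera direction up, adjusted p = 0.814), with 1 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and by limma-voom, and 1 higher and 2 lower in the blocked fit. Adjusted over the list alone, 2 oxidative stress genes were lower and 0 genes of the glycolysis, mitochondrial and unfolded protein response lists passed. Nqo1 and Me1 each lost the call without Biotin- replicate 3, and Nqo1 also without Biotin+ replicate 1 or 2 or Biotin- replicate 1. With library size alone the medians of the glycolysis, mitochondrial and cholesterol lists turned to -0.0792, -0.083 and -0.145. Under the identity scaling they were -0.707, -0.683 and -0.762, where the median of all genes was -0.741. With that scaling 11, 6 and 8 of their members were lower, as were 16 oxidative stress and 13 unfolded protein response genes, and 0 were higher.

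Of 35 type I interferon response genes, 2 were lower, 1 was higher and 32 did not pass, with negative log2 fold changes in 29 and a median of -0.47. Under the identity scaling 25 were lower and 0 higher (median -1.32). Camera called the list (adjusted p = 0.0179), and the adjusted p was 0.82 with an estimated correlation. Oasl2 (-1.76 ± 0.37 SE) and Oas2 (-2.27 ± 0.56 SE), of the oligoadenylate synthetase family that senses viral RNA, were lower, and Isg20, an antiviral exonuclease, was higher (1.06 ± 0.27 SE), the same counts as adjusted over the list alone. Oas2 was low in both groups (1.335 CPM in Biotin+ and 6.52 CPM in Biotin-). The blocked fit gave 5 lower and 1 higher. Camera no longer called the list without Biotin+ replicate 3 (adjusted p = 0.101) or Biotin- replicate 3 (adjusted p = 0.0933), and Oasl2, Oas2 and Isg20 each lost the call without Biotin+ replicate 2 or Biotin- replicate 3, Oas2 and Isg20 also without Biotin- replicate 2, and Isg20 also without Biotin+ replicate 1 or Biotin- replicate 1. Of 24 interferon gamma response genes 0 passed in edgeR, DESeq2 or limma-voom, also adjusted over the list alone, while 3 were higher and 3 lower at an unadjusted p under 0.05, and 2 higher and 4 lower in the blocked fit. The list's median was 0.11 and its mean -0.10, with opposite signs, and it was not called (camera adjusted p = 0.776). Psmb8, an immunoproteasome subunit, had a log2 fold change of 0.66 ± 0.22 (SE, edgeR adjusted p = 0.0994; 0.0274 in the blocked fit), and Gbp2, an interferon-induced GTPase, of -1.24 ± 0.48 (SE, edgeR adjusted p = 0.157; 0.000503 in the blocked fit).

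Markers of other cell types moved apart. Of 13 fibroblast and endothelial markers tested, 8 were lower and 5 did not pass, all 13 log2 fold changes were negative, and the median was -2.29. The 8 are fibroblast and matrix genes, and the endothelial members Pecam1 and Kdr, named after their values were seen, did not pass (log2 fold changes -0.81 and -1.65, edgeR adjusted p = 0.172 and 0.374). Col3a1 was 64.5 ± 40.7 CPM in Biotin+ and 393 ± 33.1 CPM in Biotin-, Sparc, a matrix glycoprotein, 79.8 ± 40.5 against 410.3 ± 99.5 CPM, Col1a1 25.5 ± 7.33 against 191 ± 77.9 CPM, and Dcn, the proteoglycan decorin, 22.4 ± 3.18 against 125 ± 12.7 CPM (SD, n = 3, log2 fold change of Dcn -2.48 ± 0.20 SE, edgeR adjusted p = 0.00213). The camera adjusted p was 7.17e-17, and the adjusted p was 0.238 with an estimated correlation. In the blocked fit 11 were lower, as when adjusted over the list alone. Col1a1, Col3a1, Dcn and Sparc passed without each library and each same-numbered pair.

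Macrophage and monocyte markers had negative log2 fold changes in 24 of 24 members, with a median of -0.92. The 2 that passed, also adjusted over the list alone, were Pla2g7, a secreted phospholipase (-1.77 ± 0.25 SE), and Spp1, osteopontin (-1.45 ± 0.26 SE), 8 were lower in the blocked fit, and 18 under the identity scaling (median -1.83). Spp1 lost the call without Biotin+ replicate 2. Camera called the list (adjusted p = 0.000224), and the adjusted p was 0.82 with an estimated correlation. Camera did not call the list without Biotin+ replicate 3 (adjusted p = 0.0934) or Biotin- replicate 1 (adjusted p = 0.126), where its median was -0.212.

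The other cell type lists were not called. Of 8 epithelial and tumour cell markers 2 were lower, Cav1, a caveolar protein (-2.54 ± 0.39 SE), and Cd9, a tetraspanin (-1.19 ± 0.27 SE), and 1 was higher, Spint2, a protease inhibitor (0.95 ± 0.20 SE), against 4 lower and 1 higher adjusted over the list alone and 3 lower and 2 higher in the blocked fit (median -0.50, camera adjusted p = 0.209). Of 13 dendritic cell and MHC class II markers 1 was lower, Fscn1, an actin-bundling protein (-1.02 ± 0.25 SE), with 2 lower and 1 higher in the blocked fit (median 0.08, camera adjusted p = 0.958). Of 13 NK and gamma delta T cell markers 2 were lower, Klra4 (-2.00 ± 0.35 SE), a Ly49 receptor, and Il1r1 (-2.59 ± 0.68 SE), an interleukin 1 receptor, with 2 lower and 2 higher in the blocked fit (median 0.06, mean -0.04, camera adjusted p = 0.964). Il1r1 was low in both groups (1.25 CPM in Biotin+ and 7.54 CPM in Biotin-). Of 6 B cell markers 1 was lower, Ebf1, a transcription factor (-2.70 ± 0.56 SE), at 1.13 CPM in Biotin+ and 7.40 CPM in Biotin-. The other 5 did not pass, among them Ighm (-0.17 ± 0.26 SE), and the list median was -0.25 (camera adjusted p = 0.345). Of 9 neutrophil markers 0 passed with any of the 3 tools (median 0.13, camera direction down, adjusted p = 0.964), and 1 was lower at an unadjusted p under 0.05. Of 6 CD4 T cell markers 0 passed in edgeR or limma-voom (median 0.17, mean -0.07, camera adjusted p = 0.964), and 1 was lower by DESeq2 and 1 at an unadjusted p under 0.05. Cd4 itself was lower in the blocked fit (log2 fold change -1.58 ± 0.53 SE, edgeR adjusted p = 0.0985; 0.0353 in the blocked fit). The counts of these 5 immune lists were the same when adjusted over the list alone. Without Biotin- replicate 3 the calls of Cd9, Fscn1, Il1r1, Ebf1 and Spint2 were lost, without Biotin- replicate 1 those of Cd9, Fscn1, Il1r1 and Spint2, and without Biotin- replicate 2 those of Il1r1 and Spint2. Without Biotin+ replicate 2 the calls of Cd9, Fscn1, Il1r1 and Ebf1 were lost, without Biotin+ replicate 1 those of Cd9 and Il1r1, and without Biotin+ replicate 3 that of Fscn1.

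T cell receptor V segments were not called as a list. Of 55 tested alpha and beta V segments 0 passed in edgeR, DESeq2 or limma-voom, also adjusted over the list alone, while 1 was lower at an unadjusted p under 0.05, and 3 were higher and 1 lower in the blocked fit (median 0.35, camera adjusted p = 0.814). Under the identity scaling camera called the list (adjusted p = 3.34e-06), with 2 members lower. Its median was then -0.463, negative but above the median of all genes (-0.741), against which camera compares a list. Trbv5 reached 37.0 ± 39.9 CPM in Biotin+ and 11.6 ± 7.99 CPM in Biotin- (SD, n = 3, edgeR adjusted p = 0.302; 0.00288 in the blocked fit), a spread between replicates as large as the mean.

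**Figure D3:**
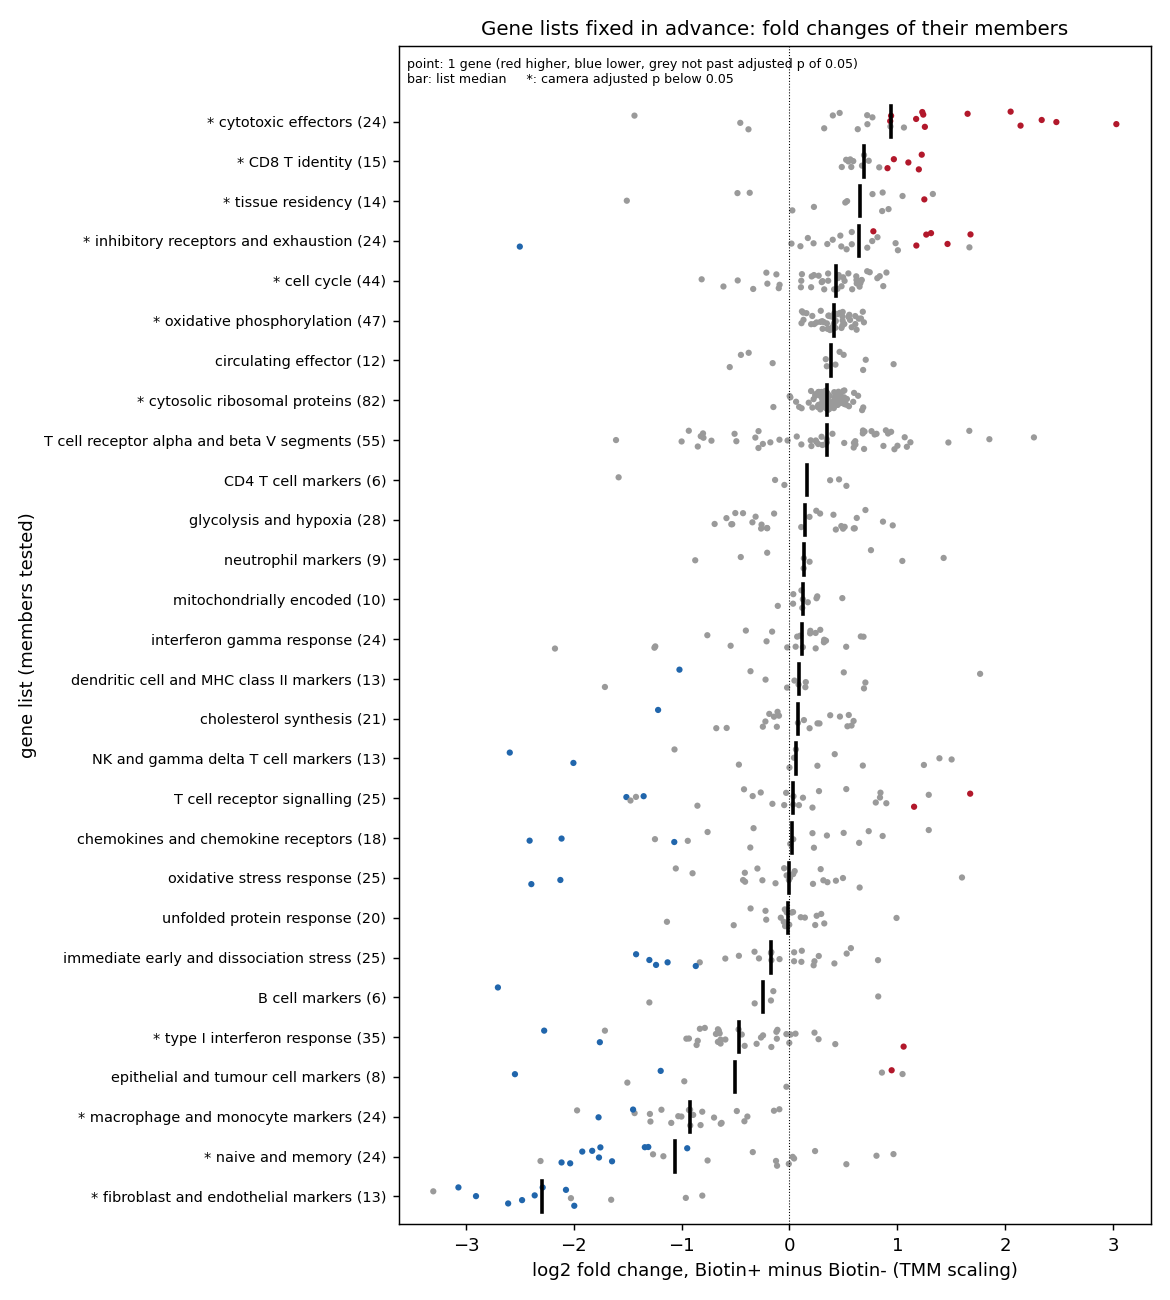
Log2 fold change (Biotin+ minus Biotin-) of each tested member of the 28 gene lists, with the number of members in brackets, a black bar at each list's median and an asterisk at lists called by camera with its preset correlation. Red and blue points are members called higher and lower, and the medians run from -2.29 for fibroblast and endothelial markers to 0.94 for cytotoxic effectors; under the identity scaling the positive medians other than that of the cytotoxic list turned negative.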

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

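The identity scaling and the offset for GC content and length, alone and with the replicate block, were tried only after the data were seen. Under each of the other settings run, the lower genes outnumbered the higher genes. In total, higher and lower, the counts of 1103, 205 and 898 became 1891, 396 and 1495 without a filter on low counts, 1836, 401 and 1435 with DESeq2, and 2347, 748 and 1599 with the replicate block, which kept all 1103 calls. An adjusted p of 0.01 gave 256, 22 and 234, and a test against a fold of 1.5 gave 489, 30 and 459. Library size alone gave 84 higher genes and limma-voom 331. The identity scaling gave 4294, 21 and 4273, and 8438, 86 and 8352 with the block, with the 898 lower genes kept in both and 20 and 66 of the 205 higher genes kept. The GC and length offset gave 330 higher genes, 174 of them shared with the 205, and with the block 2961, 1246 and 1715. With a library or a same-numbered pair left out, the total ran from 262 to 1213, the higher count from 23 to 200 and the lower count from 239 to 1044, all with fewer samples. Other scalings and the filter at CPM 1 kept each count within 1.5 times.

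Of the 28 lists, 11 were called by camera, 11 with the block, 0 with an estimated correlation with or without the block, 2 by fry, 9 to 11 with a library left out, and 10 under the identity scaling, 8 of them among the 11. Under the identity scaling the medians of called lists turned to -0.107 for CD8 T identity, -0.0977 for inhibitory receptors, -0.142 for tissue residency, -0.428 for cell cycle, -0.433 for oxidative phosphorylation and -0.487 for ribosomal proteins, and that of the V segments to -0.463; this follows from the shift of -0.802 that the scaling applies to the median of all genes, and library size alone shifted it by -0.202. With a library left out the cell cycle median ran from -0.0665 (without Biotin+ replicate 2, the cause was not tested) to 0.613. Of 364 list values under alternatives, 312 kept both sign and call or were called in neither setting, 39 lost the call and 5 gained it. Another 8 turned in sign with a call in at least 1 setting, namely the 7 medians above under the identity scaling and the cell cycle median without Biotin+ replicate 2. Among values called in neither setting, 44 changed sign as well.

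Of the 135 named genes, 65 passed, 31 of these without each library in turn and 20 also without each pair. Of 2956 values under alternatives, 2528 kept the call or were called in neither setting, 206 lost it and 215 gained it. Another 7 turned in sign with a call in the alternative, each of a gene not called in the main test: under the identity scaling ND1 (-0.58) and ND4 (-0.65), and under the identity scaling with the block ND1 (-0.58), ND4 (-0.65), ND6 (-0.69), Xbp1 (-0.51) and Il7r (-0.71). Among values called in neither setting, 83 changed sign as well. The block lost no call of a named gene or list. At this depth and with 3 samples per group, most 2-fold changes in the simulated data were not recovered (22.4%), so a gene that did not pass is not shown to be unchanged.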

Other observations

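The tests of the cytotoxic and inhibitory receptor members under the identity scaling, of fibroblast markers against the other cell type lists and of the parts of the naive and memory list were chosen after the results were seen, as were the gene families below. These tests and their bounds replaced earlier forms, also run after the results were seen: granzymes B to G against the identity list, fibroblast against dendritic cell markers alone, a count of T cell members lower in both scalings, tried with 2 bounds, and the called T cell members alone against the identity list. Of 25 tested collagen genes 17 were lower in edgeR, 4 of them members of a fixed list, and 8 did not pass (median log2 fold change -2.29, and -3.1 under the identity scaling). In other families 10 of 24 matrix proteases and their inhibitors were lower and 14 did not pass (median -1.85), as for 3 and 3 of 6 laminins (median -1.15), 5 and 20 of 25 integrins (median -0.38) and 6 and 15 of 21 Hox genes (median -2.24), which set position along the body axis. Mmp2, a gelatinase, was 54.1 ± 17.6 CPM in Biotin+ and 276 ± 67.1 CPM in Biotin-, and Timp1, an inhibitor of such enzymes, 13.3 ± 1.02 against 62.9 ± 19.3 CPM (SD, n = 3).

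Of 28 interleukin receptor genes tested, 4 were higher, 6 were lower and 18 did not pass. The higher genes were Il12rb1 (log2 fold change 1.24 ± 0.19 SE), Il3ra (1.24 ± 0.27 SE), Il2ra (1.15 ± 0.27 SE) and Il2rb (0.96 ± 0.22 SE), the last 2 being chains of the interleukin 2 receptor. The lower genes were Il11ra1, Il17rc, Il1r1, Il1rap, Il1rl1 and Il6ra. Socs2, a suppressor of cytokine signalling, was higher (1.49 ± 0.31 SE) and the only member of its family of 8 that passed in edgeR, while DESeq2 and limma-voom each gave 2 higher and 1 lower. Of 17 aminoacyl-tRNA synthetases 0 passed in edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (median 0.08). Under the identity scaling the median of the interleukin receptors went from 0.23 to -0.577.

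Of the cytotoxic and inhibitory receptor lists 18 members were higher in Biotin+, while 5 of 15 T cell identity genes were higher too, so dilution of T cell RNA in the Biotin- libraries is a candidate explanation. It cannot be told apart from a change within T cells for the 18 called members as a set: under the identity scaling 6 of them still passed (Gzmb, Gzmc, Gzmf, Prf1, Pdcd1 and Tnfrsf9), and 10 with the replicate block (Gzmd and Gzme among the others), on either side of the bound of 9. Their median log2 fold change was 1.29 before that scaling, 0.526 after it and 0.521 with the block too, and their median SE 0.277, 0.261 and 0.193, so the calls ended with the smaller fold changes and not with a wider spread. GC content and transcript length argue little for the pattern, since 17 of the 18 members still passed with the offset that removes both trends. What stays open is a difference in state between cells near and far from the tumour, which the design names, and a different mix of T cells in the sorts.

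Fibroblast and matrix transcripts were lower in Biotin+, and unequal carry-over of RNA or cells of another type may be the source. The 13 tested markers deviated together within groups (mean pairwise correlation 0.247, percentile 99.43 among 10000 random lists matched on expression, whose median was -0.0143), as a shared source would give, in spite of the sort on CD8. A comparison with random lists cannot tell a shared source from genes that move together for another reason. A lower purity that raises every other cell type alike would give equal list medians. The fibroblast median lay below that of each of the 7 other cell type lists, from -1.37 relative to macrophage and monocyte markers (permutation p = 2e-05, adjusted p = 0.00014, 2-sided, 100000 resamples, over genes) to -2.45 relative to CD4 T cell markers (exact permutation p = 0.00103, adjusted p = 0.00181), with adjusted p of at most 0.00306. These p-values treat genes as independent, though the markers deviated together, and do not measure the spread between libraries. Some markers were about as abundant in Biotin+, such as Tnfsf11 (71.9 against 52.3 CPM) and Ighm (54.1 against 60.9 CPM). Added RNA in Biotin- moves such markers less, so the test cannot decide. The most abundant markers reached 796 ± 509 CPM (Fn1, named after its values were seen), 410.3 ± 99.5 CPM (Sparc) and 393 ± 33.1 CPM (Col3a1) in Biotin- (SD, n = 3), 9 of the list's genes had a mean CPM of at least 10, 0 of its 18 genes are in another list, and macrophage markers were negative too, by less (median -0.92). Whether mesenchymal tumour cells, fibroblasts or their debris carried them, and whether this depends on the position of the T cells, was not tested.

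Of 24 naive and memory genes 10 were lower in Biotin+, and part of them could have come with the same fibroblast-like RNA. For the 12 tested members that T cells use and stromal cells do not, taken as a set, the bounds cannot decide. Their median log2 fold change, at -0.811 relative to that of the identity list, lay between the bounds set for either answer. The set did lie below the identity list (permutation p = 4e-05, 2-sided, 100000 resamples, over genes), which carried-over RNA alone would not give. That test treats genes as independent and does not measure the spread between libraries. The SD of the single members was 0.949, which is not a test of the difference. Of these 12, 3 were lower in both scalings, among them Tcf7 and Slamf6 (the latter named after its values were seen), and 9 were not called lower in the main test. Under the identity scaling 5 of the 12 were lower and 0 higher. For the 7 called members that stromal cells also use, such as Klf2 and S1pr1, it cannot be told apart because their median log2 fold change lay 0.534 above that of the fibroblast list, also between its bounds. These 7 of 12 tested members were picked for being lower, which draws their median toward that of the fibroblast list. A lower share of stem-like or recently arrived cells among the Biotin+ cells stays open as a biological explanation, which these data did not test.

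The split of the 6 libraries by biotin gave 205 higher and 898 lower genes, and the highest of the other 9 splits gave 0. In both directions 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Of the 4 splits that part all same-numbered pairs, the other 3 gave 0 genes.

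T cell receptor beta V segments tied samples with the same number to each other. Across 25 segments, the shares of Trbv counts correlated at 0.814, 0.979 and 0.773 (Pearson, across genes, which are not independent) for same-numbered Biotin+ and Biotin- libraries, and at 0.183 to 0.607 for the 6 other combinations. Trbv12-2 took 42.3% and 39.6% of the Trbv counts in replicate 2, against 10.1% to 16.9% in the other libraries. Trbv20 took 29.8% and 17.7% in replicate 3, against 0.0864% to 3.27% in the others. Such differences argue against technical replicates drawn from a single pool of cells, while the labels do not say whether a number marks an animal. The segment shares were looked at after the data were seen.

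The hypothesis that usage is narrower in Biotin+ was tested on the Shannon diversity of Trbv usage, from 4540 to 8053 Trbv counts per library. Its mean in Biotin+ minus that in Biotin- was -0.399 bits (exact permutation p = 0.2, 2-sided, where 3 against 3 cannot go below 0.1). The ranges overlapped, since Biotin+ replicate 1 (3.44 bits) lay above Biotin- replicate 2 (3.39 bits), while within same-numbered pairs the differences were -0.418, -0.319 and -0.46 bits. Overlapping ranges had been set beforehand as the outcome that counts against the hypothesis, but that bound ignored that the numbers pair the samples, and in each of the 3 pairs the Biotin+ value was the lower. The permutation test did not use the pairs and cannot go below 0.1, so it cannot decide.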
